A study of Mus musculus with 4 samples.

How the data were processed

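RNA of epigonadal white adipose tissue from fasted male mice was converted to biotin-labelled single-stranded DNA and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The 4 groups, taken from the source names in the labels, were the Irs1/2-flox control, LDKO (Irs1/2-flox with Albumin-Cre), the Irs1/2:FoxO1-flox control and LTKO (Irs1/2:FoxO1-flox with Albumin-Cre), with 1 array each. The labels do not say whether an array holds RNA of 1 mouse or a pool.

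The deposited values are log2 signals per probe set that the authors made with Affymetrix Expression Console and the RMA method (background correction, quantile normalization and a summary over probes), per the submitters' processing notes; versions are not given in the sources used here. The medians of the 4 arrays were 4.70, 4.73, 4.68 and 4.69 in the order above. The sorted values of the arrays are close but not identical. Since the summary over probes follows the quantile normalization, this does not tell which arrays were normalized together, and that set is not known. RMA removes a shift of all genes together, and it compresses differences of dim probes, so differences of genes near the background understate the true size.

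Of 41345 probes, 23521 have 1 gene symbol, 1814 have several and 16010 are unnamed here. Symbols were updated through gene identifiers to the GRCm38.p6 annotation, which held 23328 of the probes with 1 gene and was used only for names and for which genes neighbour each other. A gene was the probe with exactly 1 symbol that had the highest mean over the 4 arrays, which gave 22180 genes, 1082 of them with several probes. Probes with several symbols were left out.

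Differences were LDKO minus the Irs1/2-flox control, LTKO minus the Irs1/2:FoxO1-flox control, the Irs1/2:FoxO1-flox control minus the Irs1/2-flox control, and the LTKO difference minus the LDKO difference. With no replicates there was no test. Genes were described by size, at least 1 on the log2 scale, among those whose highest array in the comparison reached the median gene (5.15). Correlations across genes are descriptions. The design, the size rule, 41 gene lists of pathways, cell types and neighbouring tissues, and the rule for named genes were fixed before the data were examined. That rule took the 10 genes with the largest positive and the 10 with the largest negative difference past the filter for LDKO and LTKO, the 5 each way for the other comparisons, Irs1, Irs2, Foxo1, Fst, Lep and Adipoq, and up to 4 members of a list that stood apart and up to 2 of others, by size of difference, without predicted genes, clone names, small RNA genes and chemoreceptor genes. Further list members, genes that set 1 array apart from all others, and genes that separate the floxed lines were chosen for the text after their values were seen.

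The lists hold 837 symbols, of which 752 were measured, 705 distinct genes, and 85 were not matched. Members with a mean at or above the median gene entered, and the median difference of a list was set against 10000 random lists of the same size drawn from the 11090 such genes within 10 classes of mean expression. A list stood apart where its median lay outside the central 95% of random lists. Of the 41 lists 37 had at least 4 such members. The percentiles describe these arrays and are not p-values.

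The scripted steps were tested on simulated data with noise of SD 0.2 per array. For LDKO against its control, 94% of genes planted at a log2 difference of 1.5 and 100% of those at 2.0 were recovered, with 4 unplanted genes past the threshold among 11575. A shift of 0.3 planted in the oxidative phosphorylation list was found in 20 of 20 simulations, a shift of −0.3 in the mesothelial list in 18 of 20, and 4% of 200 unchanged lists lay outside the central 95%. The noise was drawn independently for each gene, so these rates check the steps and are not error rates of the real arrays. Between the 2 control arrays 88 genes were 2-fold apart and 17 of 37 lists stood apart.

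Alternatives were thresholds of 1.5-fold and 3-fold, no filter and a filter at the 70th percentile, the mean of all probes of a gene, quantile normalization again, removal of a loess curve with a span of 0.3, and the mean of both controls as reference. For the lists they were all measured members, the mean, unmatched random lists and leaving out the member with the largest difference. The other control as reference, LTKO directly against LDKO for genes and lists, the lists with a loess curve removed, and a count without tissue lists were added after the data were seen, as were a motile cilia list and an imprinted gene list. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.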

Results

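Gene expression was measured in epigonadal white adipose tissue, the visceral fat pad beside the testis and epididymis, of fasted male mice, with 1 array for each of 4 genotypes. LDKO mice lack the insulin receptor substrates Irs1 and Irs2 in hepatocytes, through a Cre recombinase driven by the albumin promoter, and LTKO mice lack the transcription factor Foxo1 there as well. Each Cre line was set against the floxed line without Cre that carries the same floxed genes, called here the Irs1/2-flox control and the Irs1/2:FoxO1-flox control. The LDKO and LTKO mice were 4 months old, and the labels give no age for the control mice, so a difference in age is not ruled out in any comparison with a control. The albumin promoter directs Cre to hepatocytes, and whether the floxed genes are intact in fat was not tested here. With 1 array per group, no difference below has a replicate check, a standard error or a p-value, and the number of arrays limits the precision of every value. The arrays held 22180 genes, and Pearson's r across genes between pairs of arrays ran from 0.986 to 0.991. Values are log2 units, differences are Cre line minus control, and 1 unit is 2-fold. A gene list is said to stand apart where its median lies outside the central 95% of random lists of like expression.

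The targeted genes were read first, although their levels in fat do not check a deletion made in liver. Irs2 was 7.96 in the Irs1/2-flox control, 7.62 in LDKO, 7.93 in the Irs1/2:FoxO1-flox control and 7.79 in LTKO. Foxo1 lay between 8.02 in LDKO and 8.37 in the Irs1/2:FoxO1-flox control. Irs1 was 6.96 and 7.46 in the Irs1/2-flox control and LDKO, a direction on which its 2 probes differed, and 7.86 and 7.09 in the Irs1/2:FoxO1-flox control and LTKO. Fst, the activin-binding protein follistatin, was 6.30 in LDKO and between 6.78 and 6.89 in the other arrays.

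The first comparison asks how fat differs when the liver cannot signal through Irs1 and Irs2. Among the genes far lower in LDKO than in its control were the imprinted gene Zim1 at −3.75, its imprinted neighbour Peg3 at −2.28, Mest, an imprinted marker of adipocyte enlargement, at −1.87, and Sfrp5, a secreted Wnt inhibitor, at −1.38, although other markers of fat pad expansion, such as Bmp3 at 1.41, were higher. Thbs2, a matrix glycoprotein, differed by −3.34, the transcription factor Irf4 by −2.67 and Vnn1, a pantetheinase, by −2.61. Most genes of fat synthesis and all those of mitochondrial respiration on the lists were higher, among them Thrsp by 1.29 and cytochrome c (Cycs) by 1.18, which were also 2-fold higher than the other control. Pnpla3 was higher by 1.92 and fatty acid synthase Fasn by 1.47, but by 0.81 and 0.47 against the other control, and Fasn was 2-fold lower in the Irs1/2-flox control than in all 3 other arrays. The leptin gene Lep was higher by 0.85, and adiponectin (Adipoq) by 0.08.

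In all, 66 genes were at least 2-fold higher and 72 at least 2-fold lower in LDKO, of 11533 genes past the filter on dim genes. The 2 control arrays differed from each other by as much at 88 genes, 30 higher and 58 lower in the Irs1/2:FoxO1-flox control. The genes with the largest positive differences also included Cyp2f2 (2.84 by its brighter probe, 0.57 by the other), the lactate receptor Hcar1 (2.48), the serpin Serpina3b (2.19), the mitochondrial dicarboxylate carrier Slc25a10 (2.07), Aldh1a7 (2.06), Lrrc39 (2.01), the adhesion molecule Ncam2 (1.95) and Lctl (1.87). Rnase2a was higher by 2.11, but it was higher by 2.10 in the Irs1/2:FoxO1-flox control as well, so its low value belonged to the Irs1/2-flox control array. Also far lower were Gprin3 (−2.33), the sialyltransferase St6galnac5 (−2.07), Adap2 (−2.00) and the chemerin receptor Cmklr1 (−1.93). Myosin heavy chain Myh4 differed by −2.62 from its own control and by 0.38 from the other control.

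**Figure D1:**
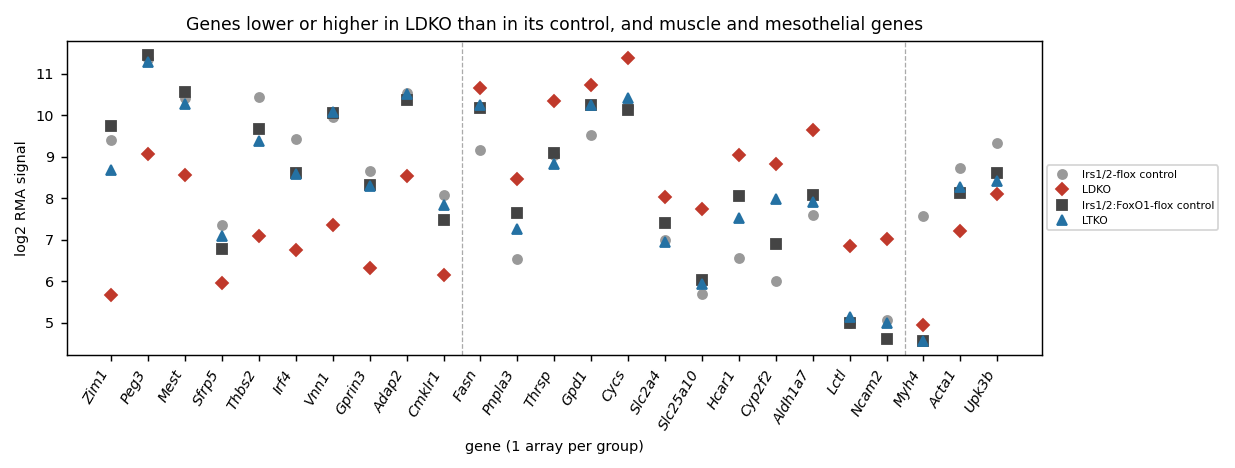
Log2 RMA signal (vertical axis) of named genes (horizontal axis) in the 4 arrays, 1 symbol per array, with genes lower in LDKO on the left, genes higher in LDKO in the middle and muscle and mesothelial genes on the right. Zim1 lay at 5.66 in LDKO and between 8.69 and 9.75 in the other arrays, whereas Myh4 lay at 7.57 in the Irs1/2-flox control alone.

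All 27 oxidative phosphorylation genes were higher in LDKO than in its control, by a median of 0.53, with Cycs at 1.18, and the complex I subunits Ndufb3 at 2.06-fold, Ndufs1 at 0.80 and Ndufa1 at 0.77. The list lay at percentile 100 of 10000 random lists matched on expression. Of 22 fatty acid and triglyceride synthesis genes, 6 were at least 2-fold higher (Pnpla3, Fasn, Thrsp, Gpd1, Me1 and Agpat2) and 8 were lower, among them Gpam (−0.75), and the median was 0.63. Fatty acid oxidation had a median of 0.49 over 21 genes, with Acadvl at 0.83 and Cpt2 at 0.70, and glycolysis and the TCA cycle had a median of 0.44 over 21 genes, with the insulin-regulated glucose transporter Slc2a4 at 1.03, Idh3a at 0.89 and citrate synthase Cs at 0.80. The 11 adipose expansion genes were split, since the median was 0.46 with Bmp3 at 1.41 and Lep at 0.85, while Peg3, Mest and Sfrp5 were the 3 members at least 2-fold lower. Smaller positive medians that also lay above the central 95% of random lists were those of dendritic cell and MHC class II genes (0.22, with all 7 members higher), lipid uptake (0.20, with Fabp5 at 1.01), cholesterol synthesis (0.16, with Insig1 at 1.24), lipid-associated macrophage markers (0.14) and collagens and matrix (0.11, with Col15a1 at 1.78).

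Several groups were lower in LDKO. Skeletal muscle genes had a median of −0.86 over 11 genes, with Acta1 at −1.52, and mesothelial markers, genes of the membrane that covers the fat pad, had a median of −0.66 over 15 genes, with Upk3b at −1.22. Glucocorticoid-responsive genes had a median of −0.53 over 16 genes, with Errfi1 at −1.17 and the metallothionein Mt2 at −0.81. Of 20 macrophage markers, 18 were lower (median −0.30), led by the resident macrophage gene Folr2 at −1.16 and Retnla at −0.94. Immediate early genes (median −0.27, Fosl2 at −0.91), stromal progenitor markers (−0.27, Dpp4 at −0.77) and FoxO and fasting-responsive genes (−0.23, Fbxo32 at −0.95) also lay below the central 95%. The adipocyte marker list was just within the central 95% of random lists, at 0.12 (percentile 97.33), with 15 of 18 genes higher. The interferon, lipolysis, adipokine, endothelial and hypoxia lists were within it too.

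Part of this contrast belonged to the Irs1/2-flox control array. Between the 2 arrays without Cre, 17 of the 37 lists stood apart, as many as in LDKO. Standing apart is thus not by itself a sign of the genotype. Of the 17 lists apart in LDKO, 10 were apart in the same direction when the Irs1/2:FoxO1-flox control was set against the Irs1/2-flox control, and 6 stayed apart when LDKO was set against the other control: oxidative phosphorylation (0.29), adipose expansion (0.29), dendritic cells and MHC class II (0.22), lipid-associated macrophages (0.21), glycolysis and TCA cycle (0.14) and fatty acid oxidation (0.12). Against that control the fat synthesis list was at 0.05, the mesothelial list at −0.08 and the skeletal muscle list at −0.16, all inside the central 95%, and the immediate early list was at 0.21, in the opposite direction. Of the 66 higher genes 31, and of the 72 lower genes 31, were 2-fold apart against both controls.

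**Figure D2:**
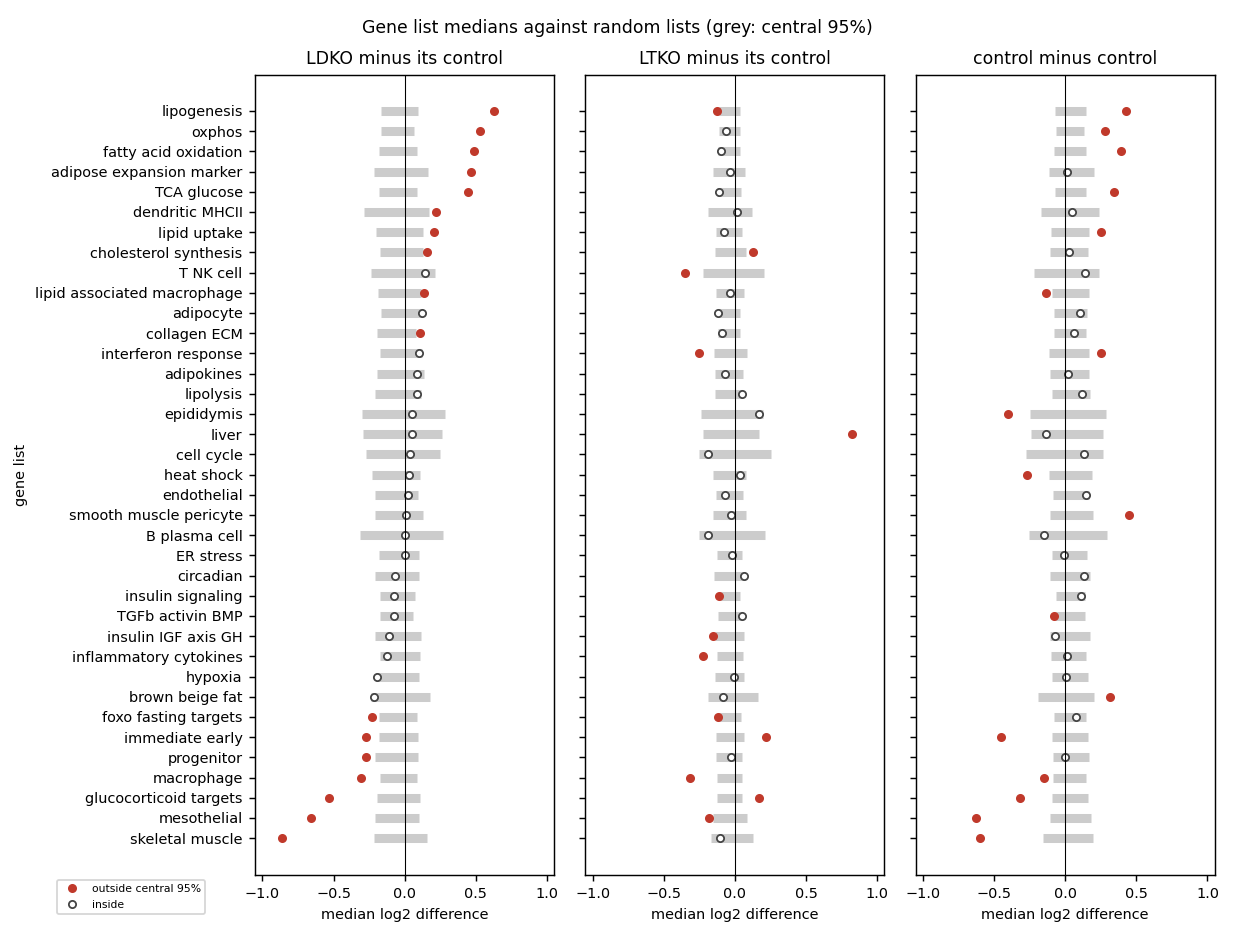
Median log2 difference (horizontal axis) of each of 37 gene lists (vertical axis) for LDKO minus its control, LTKO minus its control, and the Irs1/2:FoxO1-flox control minus the Irs1/2-flox control, with the central 95% of 10000 matched random lists as grey bars and lists outside it as filled points. The fat synthesis list lay at 0.63, −0.13 and 0.43 in the 3 panels, and the liver list at 0.83 in the LTKO panel.

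The second comparison asks the same of mice whose hepatocytes lack Foxo1 along with Irs1 and Irs2. The genes highest in LTKO relative to its control were genes of the epididymis, of sperm and of liver: the epididymal glutathione peroxidase Gpx5 by 5.31, the epididymal lipocalin Lcn9 by 3.18, the sperm mitochondrial protein Smcp with 6.17 against 3.17, the fatty acid hydroxylase Cyp4a14 by 3.51, the serpin Serpina1c by 3.17 and albumin (Alb) by 2.89. Zim1 differed by −1.06, and Lep was higher by 0.74. Macrophage and interferon genes were lower, with medians of −0.31 and −0.25. None of the 22 fat synthesis genes was 1.5-fold apart.

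In LTKO 200 genes were at least 2-fold higher and 5 were at least 2-fold lower, of 11533 genes. Against the other control these counts were 97 and 47, and with the filter at the 70th percentile 81 and 2. Others among the highest were Adam5 (3.06), a gene of the sperm surface, the liver glycoprotein Ahsg (2.73), Rgs22 (2.58) and the beta-defensin Defb48 (2.58). The lowest named genes were the neuroglobin gene Ngb (−1.14), the amino acid transporter Slc43a1 (−1.08), Zim1, the G protein regulator Rgs2 (7.63 in LTKO, 8.63 in its control, with −0.03 by its other probe), Cd209g (−0.98), Igh-VS107 (−0.98, with 0.59 by its other probe), the macrophage receptor Vsig4 (−0.96), liver-type glycogen synthase Gys2 (−0.94), Isl1 (−0.94) and H2-T24 (−0.93). Over all measured members, 7 of 27 epididymis genes, 7 of 15 testis genes and 7 of 15 liver genes were at least 2-fold higher in LTKO, and none of them was so in the Irs1/2:FoxO1-flox control against the Irs1/2-flox control. Transition protein Tnp2 was higher by 2.39, and apolipoprotein Apoa1 was 2.82-fold higher. All 200 higher genes were also higher against the other control, 75 of them at least 2-fold. Both comparisons share the LTKO array on which these genes were picked, so the shared sign is not an independent check.

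**Figure D3:**
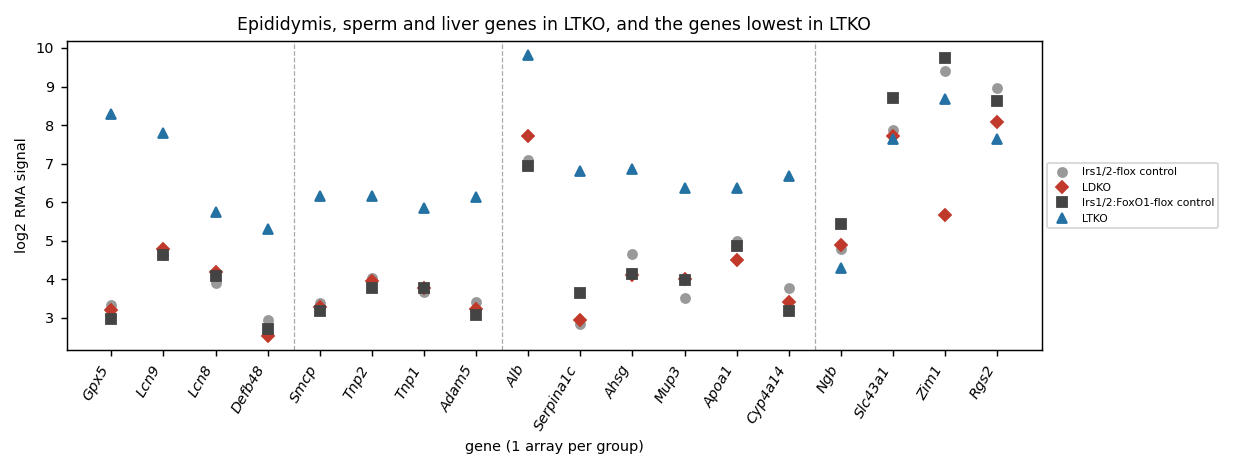
Log2 RMA signal (vertical axis) of named genes (horizontal axis) in the 4 arrays, 1 symbol per array, from left to right epididymis genes, sperm genes, liver and related genes, and genes lowest in LTKO. Gpx5 lay at 8.28 in LTKO and between 2.97 and 3.32 in the other arrays, and Alb at 9.82 against 6.93 to 7.70.

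Of 20 macrophage markers, 18 were lower in LTKO, with Lyz1 at −0.83 and Cd68 at −0.64, and the list lay at percentile 0.00 of random lists. Of 17 interferon-responsive genes 15 were lower, with Iigp1 at −0.88, Ifit3 at −0.86 and Oasl2 at −0.80. T and NK cell markers (median −0.35 over 6 genes, Ccl5 at −0.47), cytokines and chemokines (−0.22, Cxcl9 at −0.55, with Lcn2 at 0.84), growth hormone and IGF axis genes (−0.15), fat synthesis (−0.13), FoxO and fasting-responsive genes (−0.12) and insulin signalling components (−0.12) were below the central 95% too. The mesothelial list was split, with a median of −0.18 while Cdh1 was higher by 1.26 (0.43 by its other probe) and Krt8 by 0.91. Besides liver genes (0.83), the lists above the central 95% were immediate early genes (0.22, Egr1 at 0.75 and Fos at 0.73), glucocorticoid-responsive genes (0.17, Mt2 at 0.49) and cholesterol synthesis (0.13). Oxidative phosphorylation (−0.06), fatty acid oxidation (−0.10) and the adipocyte list (−0.12) were inside the central 95%, the adipocyte list only just (percentile 2.85).

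Against the other control, 5 of the 13 lists kept their side, those of macrophages (−0.48), mesothelial cells (−0.52), cytokines (−0.22), interferon response (−0.21) and liver (0.61). The fat synthesis (0.35), insulin signalling (0.04), glucocorticoid (−0.15) and immediate early (−0.09) lists had the opposite sign there.

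The third comparison set the 2 effects side by side, to ask what the added loss of hepatic Foxo1 does to the differences seen in LDKO fat. Hcar1 had the most negative difference of effects among named genes, −3.03, with 2.48 in LDKO and −0.55 in LTKO, and −1.53 with LTKO set directly against LDKO. Pnpla3 (−2.31, directly −1.20), Gys2 (−2.24, directly −0.89), Aldh1a7 (−2.23, directly −1.75) and Nabp1 (−2.17, directly −1.37) followed, and the most positive values were those of Gpx5 (5.43), Cyp4a14 (3.88), Ahsg (3.29) and Adam5 (3.24), genes high in the LTKO array, and Cdr1 (3.15, directly 1.43), which differed by −1.72 between the 2 controls. All 27 oxidative phosphorylation genes had a lower effect in LTKO than in LDKO, by a median of −0.63, followed by fatty acid oxidation (−0.61), fat synthesis (−0.60) and glycolysis and the TCA cycle (−0.50). Also apart on this side were T and NK cell markers (−0.48), lipid uptake (−0.30), adipocyte markers (−0.26) and collagens and matrix (−0.24). Adipokines (−0.21), interferon response (−0.20) and lipid-associated macrophages (−0.19) were so too. These values hold the difference between the 2 controls: with LTKO set directly against LDKO the medians were −0.35 for oxidative phosphorylation, with 26 of 27 genes lower, −0.18 for fatty acid oxidation, −0.10 for fat synthesis and −0.24 for glycolysis and the TCA cycle. The direct values in turn hold any difference between the 2 floxed lines.

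Lists with a higher effect in LTKO were liver (0.94), skeletal muscle (0.61), glucocorticoid-responsive (0.57), mesothelial (0.54), epididymis (0.50), immediate early (0.44) and circadian genes (0.24). Directly, liver was at 0.72, glucocorticoid-responsive genes at 0.30 and smooth muscle and pericyte genes at 0.42, while skeletal muscle was at −0.16 and the mesothelial, epididymis, immediate early and circadian lists were inside the central 95%. For smooth muscle and pericyte genes the direct value was close to the 0.45 between the controls. Against their own controls that list was at 0.01 in LDKO and −0.03 in LTKO. Only 4 of the 27 measured epididymis genes entered, since the filter on the mean drops genes that are high in 1 array alone. Over all 27, 7 were at least 2-fold higher in LTKO than in its control and 0 lower, and the direct median does not cover most of them.

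The effects were at least 2-fold apart at 480 genes of 11958, 350 with the higher effect in LTKO and 130 with the higher effect in LDKO. When LTKO was set directly against LDKO, without the controls, 246 genes were 2-fold apart. That count takes in genes that separate the floxed lines, such as Zfp982 (4.50 in LDKO and 6.58 in LTKO). Across the 11108 genes past the filter in both comparisons, Pearson's r of the LDKO and LTKO differences was −0.04 and Spearman's rho −0.03; genes are not independent replicates. Of 56 genes 2-fold higher in LDKO, 1 was also 2-fold higher in LTKO, Cyp2f2 (2.84 and 1.07 by its brighter probe), against 0.555 by independence, and of 66 lower genes 1 was also lower, Zim1, against 0.0178. Stoml3 (−1.14 and 1.67) and the tyrosine aminotransferase gene Tat (−1.18 and 1.39), named after their values were seen, were lower in LDKO and higher in LTKO. Of the 122 genes 2-fold apart in LDKO, 58 had the same sign in LTKO, and the median LTKO difference turned to the LDKO sign was −0.01. In the mirror, 29 of 113 genes had the same sign, with a median of −0.17.

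**Figure D4:**
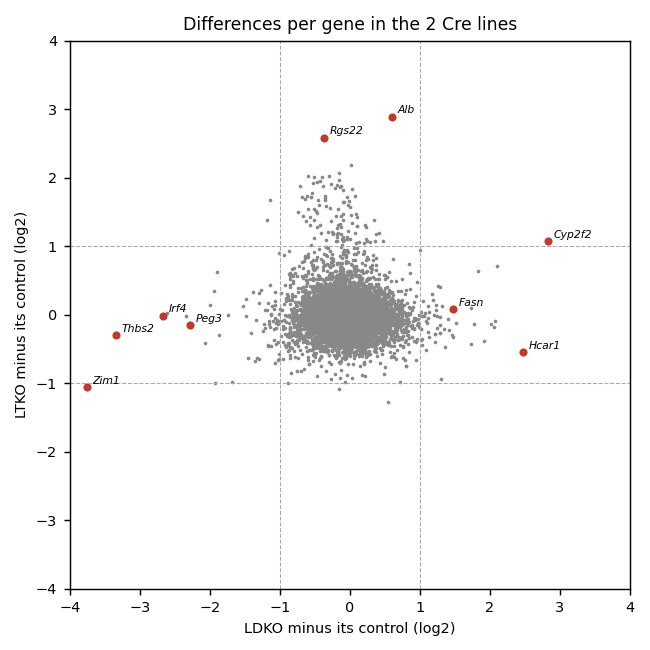
LDKO minus its control (horizontal axis, log2) against LTKO minus its control (vertical axis, log2), 1 point per gene past the filter in both, with dashed lines at 2-fold. Pearson's r across genes was −0.04, and Zim1 is the point at −3.75 and −1.06.

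Macrophage (−0.30 and −0.31), mesothelial (−0.66 and −0.18), FoxO and fasting-responsive (−0.23 and −0.12) and cholesterol synthesis genes (0.16 and 0.13) stood apart in the same direction in LDKO and LTKO, each against its own control. Against the other control none of the 4 stood apart in LDKO, and only the macrophage and mesothelial lists did in LTKO. The mean of the mesothelial list in LTKO against its own control was 0.0364, opposite in sign to its median. The fat synthesis, glucocorticoid and immediate early lists stood apart in opposite directions against their own controls only, since against the other control the LTKO medians were 0.35, −0.15 and −0.09, and the immediate early list was at 0.21 in LDKO. No test of these differences between the lines was possible with 1 array each.

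The 2 controls, which differ in the floxed Foxo1 alleles, in animal and in array, give the only gauge of how far arrays without Cre differ. The Irs1/2-flox control array held more muscle and mesothelial signal: Myh4 differed by −3.01 between the Irs1/2:FoxO1-flox control and it, titin (Ttn) was 5.71 there and at most 4.42 elsewhere, and the mesothelial list had a median of −0.62 and the skeletal muscle list one of −0.60. The fat synthesis list was 0.43, fatty acid oxidation 0.39 and oxidative phosphorylation 0.28 higher in the Irs1/2:FoxO1-flox control. Smooth muscle and pericyte genes were higher there by a median of 0.45, with Cspg4 at 0.82. Other large differences were those of Trim12c (2.58), Zfp982 (2.44), Rnase2a (2.10), Rassf6 (1.78) and Hal (1.56), and, in the other direction, the ribosomal protein gene Rps13 (−2.14), Trim12a (−1.92), Map3k7cl (−1.82) and Mmp7 (−1.60, with −0.11 by its other probe). Lep differed by −0.77, a size close to that of its LDKO and LTKO differences.

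The LDKO difference correlated with this control difference across genes at r = 0.43 and the LTKO difference at −0.53, where unchanged arrays that share 1 array gave 0.50 in size in a simulation. Genes at least 2-fold from all 3 other arrays were most frequent in LTKO, with 67 higher and 1 lower, and LDKO, with 26 higher and 22 lower. There were 5 higher and 2 lower in the Irs1/2-flox control, and 0 higher and 4 lower in the Irs1/2:FoxO1-flox control. In LDKO they included Vnn1, Peg3, Gprin3, Adap2 and Mest, lower by 1.71 or more than in any other array, and Fgf13, named after its values were seen, which was 6.35 in LDKO and at most 4.65 elsewhere.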

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

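The tests of explanations in this part were chosen after the results were seen.

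The fat synthesis, glucocorticoid and immediate early lists stood apart in opposite directions in LDKO and LTKO, each against its own control. The median over genes of the LTKO effect minus the LDKO effect was −0.60 for fat synthesis, 0.57 for glucocorticoid-responsive genes and 0.44 for immediate early genes. The choice of control carries much of this: the medians between the controls were 0.43, −0.32 and −0.45, LTKO set directly against LDKO gave −0.10, 0.30 and 0.14, and all 3 LTKO medians had the opposite sign against the other control (0.35, −0.15 and −0.0874). The difference was not tested, since each line has 1 array.

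The first pattern weighed is the set of 200 genes 2-fold higher in LTKO. Scatter of dim probes is argued against by 67 genes 2-fold above all 3 other arrays with 1 below them, where LDKO had 26 and 22, although against the other control 97 genes were higher and 47 lower. These counts overlap with the pattern itself, and the 67 genes are only part of the 200. Of the 200, 75 were also 2-fold higher against the other control, where the median of the 200 was 0.88. A low value of the Irs1/2:FoxO1-flox control array is thus not excluded for part of the pattern. The filter also lets in a dim gene that is high in 1 array but not one that is low, though without a filter 250 genes were higher and 8 lower against its own control. A candidate explanation is tissue of the epididymis or testis taken along with the fat pad, since 14 of the 42 measured genes of those lists were at least 2-fold higher in LTKO and 0 in the control difference, with Gpx5 at 8.28 and Lcn9 at 7.80. Liver RNA is another, since 11 of 13 liver genes outside the brightest genes of the other arrays, a limit set after the values were seen, were higher by 0.5 or more, with Alb at 9.82 and Ahsg at 6.85. Both stay open, as does a difference of the LTKO genotype, which was not tested.

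The second pattern is the higher fat synthesis and oxidative phosphorylation lists in LDKO. For fat synthesis, a low value of the Irs1/2-flox control array is a candidate explanation, since the median was 0.0496 against the other control (percentile 94.2) and 0.63 against its own. For oxidative phosphorylation that array cannot be the whole source, because the median was 0.29 against the other control (percentile 100), although this is below the 0.53 against its own, and an intensity trend is argued against by a median of 0.57 once a loess curve was removed. A larger share of adipocyte RNA stays open. Among lists of other cells that stood apart, macrophage (−0.30), stromal progenitor (−0.27) and mesothelial markers (−0.66) were lower. Dendritic and MHC class II (0.22) and lipid-associated macrophage markers (0.14) were higher. The oxidative phosphorylation median was 0.37 above that of the 13 adipocyte genes no brighter than the brightest gene of that list. The bootstrap interval was −0.11 to 0.54, drawn over genes, so it holds no spread between animals or arrays. The interval left out 0 against the other control at this limit (0.0037 to 0.498) and with all 18 adipocyte genes (0.15 to 0.54, and 0.0547 to 0.463 against the other control), but held 0 at every lower limit; the LDKO animal and genotype stay open too, untested.

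The third pattern is the lower Mest, Peg3, Zim1 and Sfrp5 in LDKO. A high value in the control array alone is argued against, since over the 4 genes LDKO lay at least 0.80 below both arrays of the other line. In these arrays a smaller share of adipocyte RNA is argued against by the same 13 adipocyte genes. They were higher by a median of 0.16 against the own control (bootstrap interval over genes 0.05 to 0.61) and 0.09 against the other control. A lower level of imprinted genes as a class is argued against by a median of −0.13 over 17 other imprinted genes (percentile 15.1), far from the size of the 3 imprinted ones. The state of this animal and the LDKO genotype stay open and untested, and the hypothesis that hepatic insulin signalling may bear on these 4 genes would need further animals.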

How the results depend on the processing

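The other control, the direct comparison of LTKO with LDKO for genes and lists, the loess setting for the lists and the count without tissue lists were chosen after the data were seen. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. At 1.5-fold the counts were 329 higher and 448 lower in LDKO, 409 and 100 in LTKO, 520 between the controls and 1559 for the difference of effects, and at 3-fold they were 15 and 15, 77 and 0, 12 and 148, through the threshold itself. Without a filter 8 genes were lower in LTKO. With the filter at the 70th percentile 81 were higher and 2 lower in LTKO and the difference of effects took in 281, with fewer genes entered. Against the mean of both controls 11 genes were lower in LTKO, and against the other control 97 were higher and 47 lower in LTKO and 11 lists stood apart in LDKO, and LTKO against LDKO gave 246; the cause was not tested. The remaining counts were within 1.5 times, among them 171 higher in LTKO without the epididymis, testis, liver and motile cilia lists. That count drops the listed genes only, so it cannot tell whether the other genes come from those tissues. The correlation across genes stayed between −0.05 and −0.02. Signs turned for 2 lists with the mean in place of the median (mesothelial in LTKO 0.0364, adipose expansion in LDKO −0.0417), for fat synthesis in LTKO against the mean of both controls (0.14), and, against the other control, for fat synthesis (0.35), insulin signalling (0.0375), glucocorticoid (−0.15) and immediate early genes (−0.0874) in LTKO, immediate early genes (0.21) in LDKO and Myh4 (0.38) in LDKO, and, with LTKO set directly against LDKO, for the epididymis (−0.1384) and skeletal muscle (−0.1637) lists; the cause was not tested. Under quantile normalization all 17 lists apart in LDKO and 11 of the 13 in LTKO kept their side, and of the 56 named gene differences of 2-fold all kept their size of at least 2-fold. With the mean of all probes 53 of the 56 did, and Gpd1, Cdh1 and Slc27a2 were smaller. Against the other control 34 of the 56 did, 21 were smaller and Myh4 turned. Of the 18 lists with effects apart, 10 kept their side with LTKO set directly against LDKO. The epididymis list, whose sign turned there, entered with only 4 of its 27 measured genes. Arrays give no depth, and genes near the background have compressed differences.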

Other observations

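The motile cilia and imprinted gene lists, the rule for genes that separate the floxed lines, and the tests in this part were chosen after the results were seen.

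Genes of motile cilia, the beating cilia of ductal and airway epithelia, were higher in LTKO. All 36 measured members were higher in LTKO than in its control, 15 of them at least 2-fold, with a median of 0.80, the axonemal dynein Dnah5 by 1.87, the adenylate kinase Ak7 by 1.86 and the dynein light chain Dnali1 by 1.65. The Irs1/2:FoxO1-flox control had the lowest level of the list, with a median of −0.31 relative to the Irs1/2-flox control, and LTKO lay a median of 0.59 above the Irs1/2-flox control, with 4 genes at least 2-fold higher, where the epididymis list kept 7. Hydin was 5.75, 5.48, 4.95 and 6.32 in the Irs1/2-flox control, LDKO, the Irs1/2:FoxO1-flox control and LTKO.

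Apart from Mest, Peg3 and Zim1, most imprinted genes differed little in LDKO. The largest differences were those of the amino acid transporter Slc38a4 (−0.59), Grb10, an adaptor that restrains insulin signalling (−0.50), Rasgrf1 (−0.47) and Magel2 (0.40), while Igf2 (−0.14), Cdkn1c (0.05), Peg10 (−0.06), Ndn (−0.06) and Copg2 (−0.06), which neighbours Mest, were close to their control. In LTKO Slc38a4 was higher by 1.54, at 6.35 against 4.81 in its control and 5.56 in the Irs1/2-flox control. In LDKO Slc38a4 was 4.97, so of the 2 controls it lay below the Irs1/2-flox control only. Rasgrf1 and Magel2 were below 5.15, the limit of the filter on dim genes, in all 4 arrays.

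In 17 genes both arrays of the Irs1/2:FoxO1-flox line differed 2-fold on average from both arrays of the Irs1/2-flox line, with less than 0.5 within each line. Trim12c (5.23 and 5.05 against 2.65 and 2.63), Zfp982 (2.26) and Atp1a4 (1.52) were higher in the Irs1/2:FoxO1-flox line, and Rps13 (−1.79), Slamf7 (−1.39), Mmp12 (−1.38), Saa3 (−1.19) and Il7r (−1.08) were lower. A candidate explanation is that the lines carry different strain segments: 6 pairs of the 17 lie within 100 annotated genes of each other, a number reached in 0.03% of random draws, with Slamf7, Atp1a4, Ifi203-ps and Fcgr3 together on chromosome 1. The draws took genes of any kind, so they cannot tell a segment from neighbouring genes of like function that change together. The macrophage list also stood apart between the controls, at −0.15. A segment carried along with the floxed Foxo1 allele is argued against for these genes, since 0 of them lie within 100 annotated genes of Foxo1. Whether such genes differ in level or in the sequence under their probes was not tested.

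Of 17824 probes without a single gene symbol, 6263 passed the filter on dim genes for LDKO, 6065 for LTKO and 6203 for the 2 controls. Among those, 112 were at least 2-fold higher and 117 lower in LDKO, 116 and 71 in LTKO, and 125 and 158 between the 2 controls.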
